A study of Drosophila melanogaster with 4 samples.

How the data were processed

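The samples were larval heads of Drosophila melanogaster in which the Gal4 driver repo, active in glia, was held back by the temperature-sensitive repressor Gal80ts. Per the labels' protocols, parents laid eggs for 3 days at 25 °C, larvae were then kept for 5 days at 29 °C to release Gal4, and heads were dissected on the last of these days. Total RNA was extracted with a column kit and DNase, poly-A RNA was enriched with oligo-dT beads, and libraries were made with a stranded mRNA kit. The 4 samples made up 4 groups of 1 library each. The labels do not divide them into batches, and whether they were processed together is not known here. Control larvae expressed a membrane-bound red fluorescent protein in glia. Glioma larvae also carried UAS constructs for an EGFR form and for dp110[CAAX], a membrane-tethered catalytic subunit of PI3K, encoded by Pi3K92E. The other 2 groups carried, on top of these, a UAS construct for RNA interference against Ca-alpha1T, a T-type voltage-gated calcium channel, or against slo, a calcium-activated potassium channel.

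Read counts per gene were deposited by the authors as whole numbers, per the file headers, for 11880 genes. The same table held FPKM and TPM per library, computed by the authors, per the file headers. It also held the authors' signed fold changes, p-values and adjusted p-values for 5 pairs of libraries, per the file headers. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and edgeR, and the build dm6, without saying which tool made which column. Whether counting used the strand of the reads is not given in the sources used here. Every listed gene had at least 1 count in every library, so a gene with 0 in any library is not listed. A gene that was silent in 1 group is therefore missing from the comparisons, and ratios of the genes that were turned on or off most completely cannot be given.

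Total counts were 36932553 for Control, 38826243 for Glioma, 31594447 with Ca-alpha1T RNAi and 32092414 with slo RNAi, with median counts per gene of 806, 738, 706.5 and 605. Libraries were scaled with TMM factors over the 4 libraries (edgeR 4.0.16, R 4.3.3), which were 1.06, 0.909, 1.10 and 0.939 in the same order. Scaled counts (CPM) were taken on the scaled library sizes. A log2 ratio was computed with a prior count of 0.5 scaled to library size. Its 95% interval was the exact conditional binomial interval of the ratio of 2 counts (Python 3.11.15, scipy 1.17.1). All intervals cover counting error only, and since PCR copies are not independent molecules, they may be too narrow even for that.

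With 1 library per group there is no replicate check for any difference, and no test between conditions was made. A gene was called higher or lower by a rule of size: a ratio of at least 2-fold, an interval excluding equality, and at least 10 counts in 1 or both libraries. Genes with at least 10 counts in 1 or both libraries are called detected. On simulated counts for Glioma against Control over 11880 genes with counting error alone, the rule called 31 of 11191 unchanged genes, 53.9% of genes changed 2-fold and 98.5% of those changed 4-fold. With an assumed biological coefficient of variation of 0.2 it called 282 of 11170 unchanged genes, and with 0.4 it called 2766 of 11173. The true variation between larvae of these groups is unknown, and a call therefore describes these libraries.

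All 6 pairs of libraries were compared. The 34 lists of genes, holding 942 entries, were fixed before the data were examined, and 918 entries matched a listed gene by symbol or, for older names, by NCBI gene identifier; 20 genes stood in more than 1 list. For each list the median log2 ratio of the detected members was set beside the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test of conditions. Genes are named by a rule fixed with them. It takes the manipulated genes and repo, the driver's gene, in all libraries. For the 3 main comparisons it takes the 10 called genes on each side ranked by the interval bound nearest to 0, leaving out symbols that are bare clone or RNA numbers, and up to 4 detected members of each list with the largest absolute log2 ratio. A gene that this rule did not take is said to be so where it is named.

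Comparisons that share a library are correlated without any effect. Unchanged libraries were therefore simulated 20 times at each of several assumed coefficients of variation, from the mean rates and the real library sizes. The alternatives tried were DESeq2 size factors (version 1.42.0), total counts without TMM, no filter on low counts, at least 50 counts, at least 4-fold, a prior count of 5, and the authors' FPKM and TPM with a pseudocount of 1. Gene positions were read from the Ensembl annotation of the same coordinates as dm6. The authors' p-values were not used to call genes.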

Results

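Poly-A RNA of larval heads was sequenced from 4 groups of Drosophila larvae, 1 library each: Control, Glioma, Glioma with Ca-alpha1T RNAi and Glioma with slo RNAi. A larval head sample holds brain and glia together with other tissues of the anterior larva. The comparisons ask how gene expression differs when glia express the EGFR and PI3K constructs, and how it differs again when either ion channel is targeted in those glia. Total counts ranged from 31594447 with Ca-alpha1T RNAi to 38826243 in Glioma. The mitochondrial large ribosomal RNA was the most abundant transcript in every library, at 5.75% of counts in Control, 7.14% in Glioma, 8.0% with Ca-alpha1T RNAi and 12.8% with slo RNAi.

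The transcripts of both construct genes were far above Control in all 3 glioma libraries. Egfr, the epidermal growth factor receptor gene, stood at 182 CPM in Control, 897 in Glioma, 962 with Ca-alpha1T RNAi and 651 with slo RNAi. Pi3K92E stood at 98.6, 903, 880 and 373 CPM in the same order. In Glioma against Control these were log2 ratios of 2.30 (95% counting interval 2.27 to 2.34) for Egfr and 3.20 (3.15 to 3.24) for Pi3K92E. The glial transcription factor gene repo was at 16.7 CPM in Control and at 36.6, 40.9 and 38.2 CPM in the glioma libraries, a log2 ratio of 1.13 (1.00 to 1.27) for Glioma against Control. Endogenous and construct transcripts of Egfr and Pi3K92E share a gene row, so their parts cannot be separated.

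Neither targeted channel gene reached the 2-fold rule in its own RNAi library, and the sign of the Ca-alpha1T ratio depends on the scaling. Ca-alpha1T had 506 counts in Control, 673 in Glioma, 578 with Ca-alpha1T RNAi and 536 with slo RNAi, a log2 ratio of −0.20 (−0.36 to −0.04) for the library labelled Ca-alpha1T RNAi against Glioma. On total counts this was 0.08, on the authors' FPKM 0.05 and on the authors' TPM 0.18. Total counts also moved the median of all genes, to 0.26, so Ca-alpha1T still lay below that median. For slo the counts were 902, 1208, 1154 and 753, and the log2 ratio of slo RNAi against Glioma was −0.45 (−0.59 to −0.32), with −0.38 on the authors' TPM. Both constructs act in glia, while the samples hold the transcripts of all head tissues. Egfr lies on chromosome 2R at 21522420 to 21559977, Pi3K92E on 3R at 20628972 to 20634732, Ca-alpha1T on X at 6104085 to 6192483, slo on 3R at 24662491 to 24711595, and repo on 3R at 18236192 to 18239602 (dm6 coordinates). The annotation has 5 other genes overlapping Egfr and 1 overlapping repo, so reads there may be shared among genes.

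**Figure D1:**
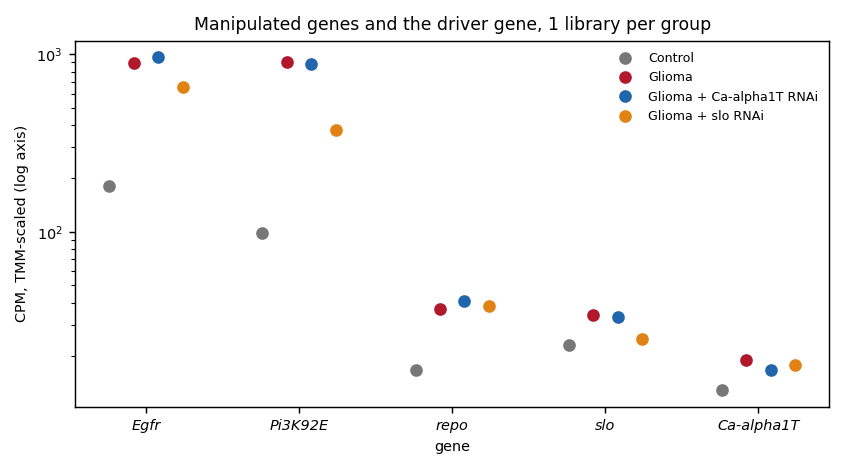
Scaled expression (CPM, log axis) of the construct genes Egfr and Pi3K92E, the glial gene repo and the targeted channel genes slo and Ca-alpha1T; each point is 1 library, so there are no error bars. Egfr lies at 897 CPM in Glioma and 651 CPM with slo RNAi, and Pi3K92E at 903 and 373 CPM.

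In Glioma against Control, the glue protein genes of the salivary gland were lower, and more genes of the ecdysone response, which times metamorphosis, were lower than higher. More members of the muscle, cuticle and glycolysis lists were higher than lower. Sgs1, a salivary glue gene, had 40355 counts in Control and 80 in Glioma, a log2 ratio of −8.82 (−9.16 to −8.51), and Sgs3 had 266901 and 6351 counts, a log2 ratio of −5.24. The antifungal peptide gene Drs had 92 counts in Control and 153512 in Glioma, a log2 ratio of 10.85 (10.56 to 11.17). The muscle myosin gene Mhc had a log2 ratio of 1.96 and the lactate dehydrogenase gene Ldh one of 1.51. By the rule of size 1152 genes were higher and 663 lower of 11410 detected.

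Of the 14 salivary genes, 9 were lower and 1 higher, and their median log2 ratio of −4.07 lay below all 10000 random lists. All 9 of the glue and Eig71E members were lower, from −9.77 for Eig71Ea to −3.26 for Sgs4 (Sgs4 chosen after its values were seen), whereas ng1, ng2 and ng3, other salivary secretion genes, had log2 ratios of 0.60, 1.05 and 0.17. The ecdysone list had 10 members lower and 2 higher of 25, with a median of −0.78 (percentile 0). Its lowest were the nuclear receptor genes Eip78C at −4.15, Hr3 at −3.44 and Hr4 at −2.90, and the transcription factor gene Eip93F at −3.22. Fat body genes went both ways, with a median of −0.07 (percentile 12.6). Fbp1, a receptor gene for larval serum proteins, stood at −3.42 and Lsp2, a storage protein gene, at −1.24, while Idgf3 stood at 1.26. The pigmentation genes e and ple had log2 ratios of −8.21 (−8.54 to −7.91) and −4.05. The transcription factor gene slbo stood at −5.67 and Muc68E, a mucin gene, at −5.10.

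All 25 muscle genes lay above 0 and 18 were higher, with a median of 1.57 (percentile 100). Unc-89 stood at 2.09, TpnC47D at 2.05 and Mlc1 at 1.90. The calcium handling genes SERCA and RyR, of which muscle makes wide use, and galene stood at 1.66, 1.77 and 2.21. The ion channel and calcium list had 6 of 43 members higher and none lower, with a median of 0.23 (percentile 99.2) that turned to −0.02 on the authors' FPKM. Of the 23 glycolysis genes 10 were higher, median 0.90, led by Ldh, Gapdh1 at 1.32 and PyK at 1.27. The 34 genes of mitochondrial respiration had a median of 0.77, with ND-75 alone passing the rule at 1.11. Of 35 cuticle and epidermis genes 18 were higher and 3 lower, median 1.10. The muscle, glycolysis, respiration and cuticle medians lay above all random lists.

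The gut list split, with 6 higher, 4 lower and 17 not called of 27, median 0.36 (interval −0.30 to 0.67). The amylase gene Amy-p stood at 3.92, and the serine protease genes Jon99Ci and Jon66Ci at 3.42 and 2.61. Other digestive and immune genes with large ratios were Jon25Biii at 4.19, Jon44E at 4.15, and PGRP-SC1a and PGRP-SC1b, peptidoglycan amidase genes, at 4.33 and 4.29. Among antimicrobial and immune genes 15 were higher and 3 lower of 30, median 1.03 (percentile 100). Next to Drs, BomS3 stood at 3.55, whereas Drsl5 stood at −5.03 and Mtk, at 2 against 68 counts, at −4.62 (−8.01 to −3.03). Detoxification genes had a median of 0.38 (percentile 99.8), with Cyp4e3 at 2.18 and Cyp6g1 at −1.80. Members of the Jon, Amy, PGRP-SC1, Sgs and cuticle families are close copies, so the split of reads among them is uncertain.

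Lists of neural progenitors and of developmental signalling had medians below 0, with few members called. The neuroblast list had 5 lower and none higher of 24, median −0.58 (percentile 0), with the transcription factor gene pros at −1.52, brat at −1.32 and erm at −1.32. Notch genes had a median of −0.60 (percentile 0; Dl at −1.11), Wnt genes −0.52 (percentile 0.02; wg at −1.26, Wnt4 at −1.17), apoptosis genes −0.50 (percentile 0.07; hid at −1.54, Dronc at −1.39) and neuronal markers −0.39 (percentile 0.02; fne at −1.27). The EGFR, Ras and MAPK list had a median of −0.29 (percentile 1.04) with 1 of 25 called, aop at −1.16. The PI3K and insulin list had a median of −0.23 (percentile 2.48), with Sesn at −1.67 and Ilp6 at −1.60. The 41 cell cycle genes had a median of −0.13 (percentile 17.2), and CycE, at −1.04, was the 1 member called.

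The 31 genes of glial identity had 3 higher and 2 lower, median 0.08 (percentile 87.4), and the pigmentation gene e, a member, had the largest ratio at −8.21. The genes moody and Mdr65, of the glial blood-brain barrier, stood at 2.74 and 2.69, and gcm at −1.67. Medians of the JNK and the JAK-STAT lists lay at 0.00 and 0.00, while the cytokine genes upd2 and upd3 stood at 2.49 (1.67 to 3.52) and 1.59 (0.97 to 2.29), and the JNK target gene Ets21C at 1.76. Hippo genes had a median of −0.39 with none called, eye disc genes one of −0.47 and hemocyte genes one of 0.00, in which NimC2 stood at −4.50. Extracellular matrix genes had a median of 0.30, heat shock genes −0.26, ribosomal proteins 0.34, ribosome biogenesis 0.16, autophagy −0.19, cytoskeleton and junction genes −0.19, transmitter receptors and peptides 0.00, and sex-linked and yolk genes 0.33. The white gene w, a common marker on inserted constructs, had 344 counts in Control and 7892 in Glioma, a log2 ratio of 4.67, and y had 15 and 205.

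Scaling by total counts moved the median of all genes in Glioma against Control by −0.23, and the calls to 46.3% higher against 63.5% with TMM. The share of calls that are higher is therefore set by the scaling, whereas the muscle, salivary and ecdysone medians kept their sign under every scaling. At 2-fold and an adjusted p below 0.05, the authors' deposited table holds 1106 genes higher and 603 lower for this pair, 1691 of them with the same call here. Those values come from the same single libraries, so the shared calls are no independent check.

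**Figure D2:**
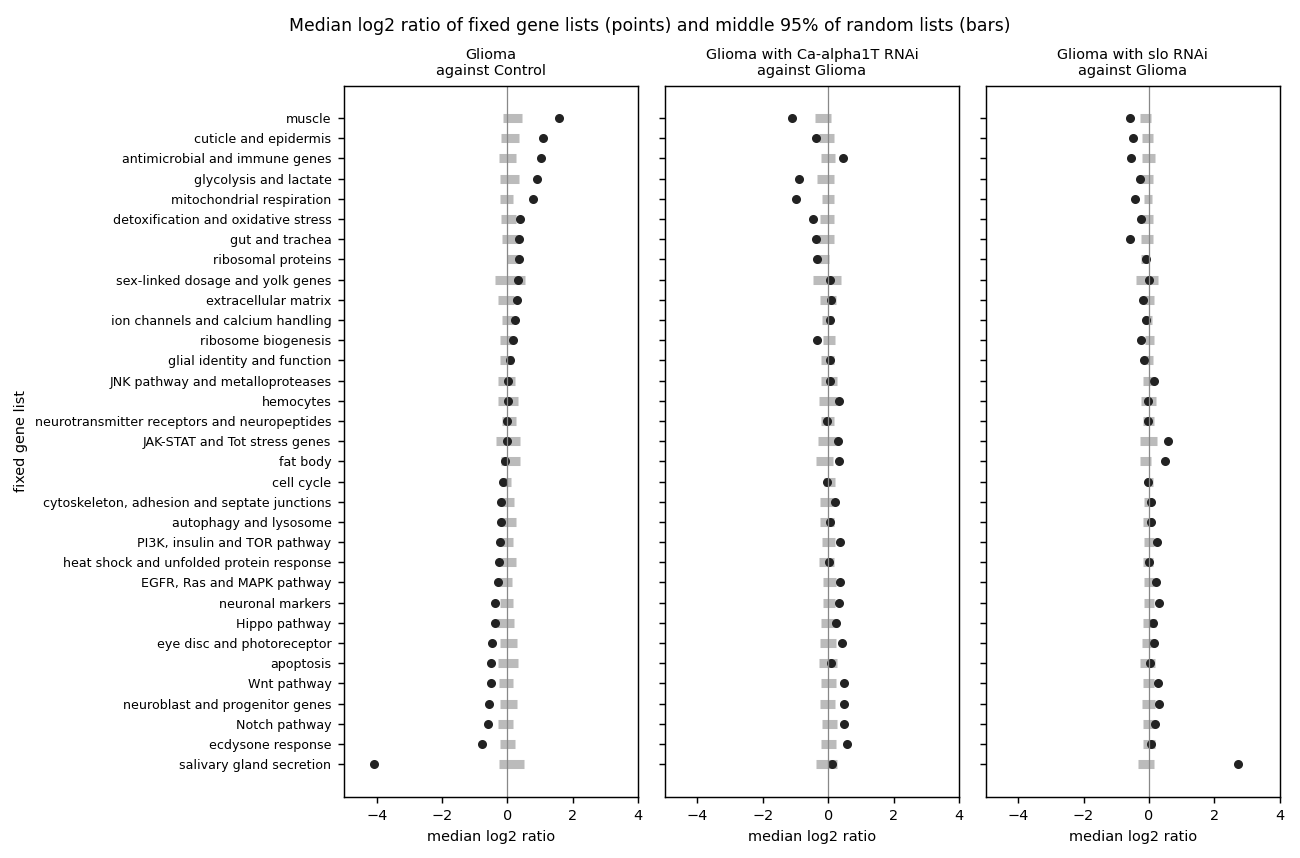
Median log2 ratio (x axis) of each fixed gene list other than the manipulated genes (y axis) in the 3 main comparisons; points are the medians of detected members and grey bars the middle 95% of medians of 10000 random lists matched on expression. Salivary genes lie at −4.07 in Glioma against Control and at 2.73 with slo RNAi against Glioma, and muscle genes at 1.57, −1.12 and −0.57.

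With Ca-alpha1T RNAi against Glioma, several antimicrobial peptide genes stood far higher and Drs far lower, and all called members of the muscle, glycolysis and respiration lists were lower. The cecropin gene CecA1 had 2 counts in Glioma and 3085 with the RNAi, a log2 ratio of 10.29 (8.76 to 13.66). Mtk stood at 7.37 (5.83 to 10.74), CecC at 6.74 (6.30 to 7.27) and AttD at 5.81 (5.47 to 6.19), while Drs had 153512 and 4046 counts, a log2 ratio of −5.22 (−5.27 to −5.18). The muscle genes Mlc2 and TpnC47D stood at −1.57 and −1.70. By the rule 562 genes were higher and 785 lower of 11405 detected.

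Of 34 antimicrobial and immune genes 15 were higher, 4 lower and 15 not called, median 0.45 (interval −0.01 to 2.25, percentile 100). Muscle genes had 13 lower and none higher of 25, median −1.12 (percentile 0). Respiration genes had 17 lower of 34, median −1.0, with COX5A at −1.18 and SdhD at −1.19, and glycolysis genes 9 lower of 23, median −0.89, with Ldh at −1.47 and Pglym78 at −1.38; both medians lay at percentile 0. SERCA, RyR and galene stood at −1.32, −1.16 and −1.31. Detoxification genes had a median of −0.46 (percentile 0.02), with GstE5 at −2.41 and GstE1 at −1.72. Among the digestive proteases, Jon65Ai stood at −4.56, Jon44E at −4.28 and Jon66Ci at −3.22. Genes with the lowest ratios also held hiro at −5.36, lcs at −5.07 and Culd at −4.48.

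The ecdysone list had 7 higher and 2 lower of 25, median 0.59 (percentile 100), with Eip78C at 2.92, Eip93F at 2.08 and Hr3 at 1.89. Salivary genes split: ng1, ng2 and ng3 stood at −2.35, −3.63 and −2.94, while Eig71Ee stood at 2.29, and the median was 0.10. Cuticle genes also split, with 9 higher and 12 lower of 35. Lcp65Af stood at 4.46 and Ccp84Aa at 2.34, against Lcp65Ab1 at −2.44 and Lcp9 at −2.29, and TwdlL, TwdlO and Cpr35B, further cuticle genes, stood at 7.40, 5.80 and 6.39. The pigmentation gene e stood at 5.38, with 3600 counts against 87. In the fat body list, Fbp1 stood at 2.71 and Lsp2 at 1.31. Neuroblast genes had 5 higher and none lower of 24, median 0.47 (percentile 100), with erm at 1.32, pros at 1.24 and brat at 1.21, and medians of the Notch, Wnt and neuronal lists were 0.48, 0.47 and 0.33. The peptide genes Pdf, Ilp5 and Crz stood at −1.73, −1.72 and −1.41. In the glial list, e was the 1 member higher and the astrocyte gene alrm, at −1.09, the 1 lower, with a list median of 0.04.

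Total counts moved the median of all genes in this comparison by 0.28 and the share of higher calls from 41.7% to 67.4%, with 975 genes higher and 472 lower. The respiration median of −1.0 lies at the 2-fold limit, so the 17 members called lower depend on the scaling too. The muscle median on the authors' TPM was −0.66.

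With slo RNAi against Glioma, more salivary and fat body genes were higher than lower, and more gut and antimicrobial genes lower than higher. Single lysozyme genes, whose products digest bacterial walls, were among the highest ratios and single Jon protease genes among the lowest. Neither family has a list of its own, and the gut list holds some members of both, LysD among them. LysD, a lysozyme gene, had 453 counts in Glioma and 63650 with the RNAi, a log2 ratio of 7.36 (7.23 to 7.50), and Sgs1 had 80 and 7180 counts, a log2 ratio of 6.71 (6.40 to 7.05). PGRP-SC1b had 13765 and 39 counts, a log2 ratio of −8.22 (−8.73 to −7.78), and Jon99Fii stood at −7.37 (−7.77 to −7.02). The construct gene Pi3K92E was lower, at −1.27 (−1.30 to −1.24), while Egfr stood at −0.46 (−0.49 to −0.44) and repo at 0.06 (−0.05 to 0.18). By the rule 504 genes were higher and 775 lower of 11389 detected.

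Of the 14 salivary genes 12 were higher and none lower, median 2.73 (percentile 100), with Eig71Ea at 4.80, Sgs5 at 3.93 and Sgs3 at 3.49. The ecdysone list had 1 higher and 3 lower of 25, median 0.06 (percentile 75.0). Fat body genes had 9 higher and 1 lower of 23, median 0.50 (percentile 100), with Fbp2 at 2.27, Fbp1 at 2.19 and Lip3, a lipase gene, at −3.77. The gut list had 10 lower and 3 higher of 26, median −0.57 (percentile 0), with Jon99Ci at −5.86 against LysB at 3.69 and, higher still, LysD. LysC and LysE stood at 7.94 and 5.57. The lysozyme genes are close copies, so their single values are uncertain. Cyp4p2, a cytochrome P450 gene, stood at 6.79.

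Antimicrobial and immune genes had 12 lower and 4 higher of 32, median −0.54 (percentile 0). DptA stood at −5.50, DptB at −4.84 and Def at −3.98, against CecC at 4.01. The JAK-STAT and Tot list had 6 higher and none lower of 14, median 0.59 (percentile 100), with the complement-like gene Tep1 at 2.04, TotC at 1.42, et at 1.36 and TotA at 1.29. Ets21C stood at 1.67 and Ilp8, an insulin-like peptide gene, at 1.36 on 60 against 27 counts. Muscle genes had 2 lower of 25, median −0.57, and respiration genes none called, median −0.41, both at percentile 0. Cuticle genes had 11 lower and 1 higher of 35, median −0.48. The neuroblast list had 1 higher and 1 lower of 24, median 0.31 (percentile 99.96), with pros at 1.25 and Imp, an RNA-binding protein gene of young neuroblasts, at −1.87. Neuronal markers had none called of 26, median 0.31 (percentile 100), and Wnt genes 1 higher of 23, median 0.26 (percentile 99.85). The glial list had none called and a median of −0.15 (percentile 4.63). The male-specific RNA genes lncRNA:roX1 and lncRNA:roX2 stood at −0.92 and −1.25. Requiring at least 50 counts left 315 genes higher.

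**Figure D3:**
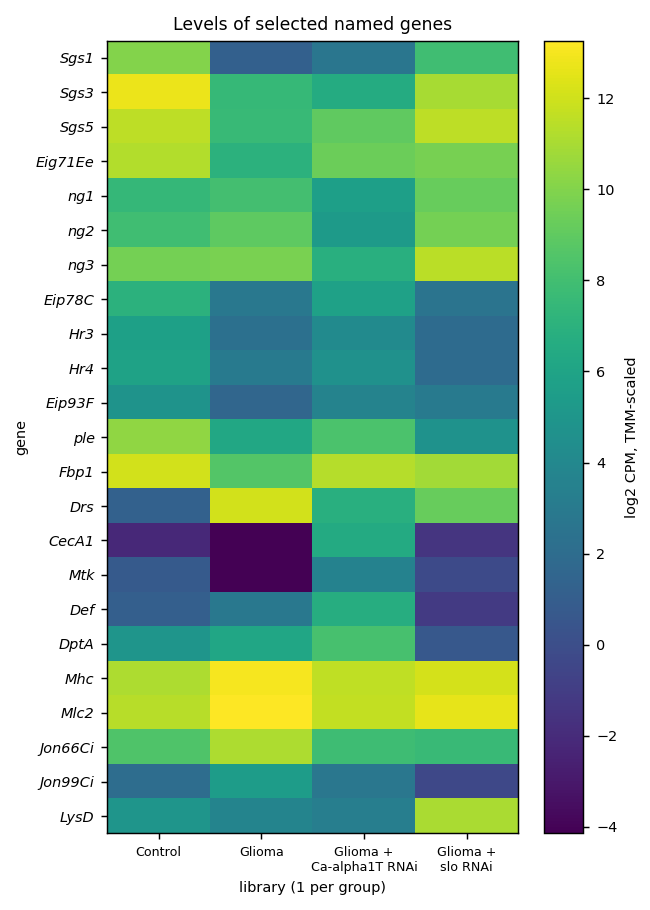
Scaled expression (log2 CPM, colour) of 23 named genes (y axis) in the 4 libraries (x axis), 1 library per group. Drs goes from 2.34 CPM in Control to 4348 in Glioma, CecA1 from 0.0566 in Glioma to 88.7 CPM with Ca-alpha1T RNAi, and Sgs1 from 1027 in Control to 2.27 in Glioma and 238 CPM with slo RNAi.

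Set directly against Control, both knockdown libraries had more salivary genes lower than higher. With Ca-alpha1T RNAi 691 genes were higher and 474 lower of 11416 detected. No muscle gene was called there, but 24 of 25 lay above 0, with a median of 0.39 (0.33 to 0.48, percentile 100). Glycolysis genes had none called and a median of 0.04 (percentile 81.9). Salivary genes had 12 lower of 14, median −2.67, and antimicrobial genes 20 higher and 2 lower of 34, median 2.12. With slo RNAi 834 genes were higher and 678 lower of 11403 detected. There muscle genes had 12 higher of 25, median 0.99, the ecdysone list 10 lower and 2 higher, median −0.56, and the salivary list 7 lower and 3 higher, median −0.83. Egfr stood at 2.40 and 1.84 against Control with Ca-alpha1T and slo RNAi, and Pi3K92E at 3.16 and 1.92. With total counts the share of higher calls for slo RNAi against Control was 41.5% in place of 55.2%.

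Between the knockdown libraries, 645 genes were higher with Ca-alpha1T RNAi and 540 lower of 11397 detected. Antimicrobial genes were higher there with 20 of 34 members and lower with 3, median 2.29, and the ecdysone list higher with 8 of 25 and lower with 1, median 0.46. Salivary genes were lower with 11 of 14 members, median −2.91, and respiration genes had a median of −0.54 with none called. Pi3K92E stood at 1.24 (1.21 to 1.27) and Egfr at 0.56 (0.54 to 0.59). With total counts the share of higher calls was 70.6% in place of 54.4%.

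None of the assumed coefficients of variation that were tried matches both the number of calls and the spread of most genes. At an assumed coefficient of variation of 0.3, simulated unchanged libraries gave 1374 calls for Ca-alpha1T RNAi against Glioma and 1366 for slo RNAi against Glioma, more than were made in either comparison, and 1360 for Glioma against Control, fewer than were made. At 0.2 they gave 301, 306 and 310. The median absolute log2 ratio was 0.34 with Ca-alpha1T RNAi and 0.28 with slo RNAi against Glioma, and 0.44 in simulated libraries at 0.3 and 0.30 at 0.2, so 0.3 is too wide for most genes.

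The position of the knockdown libraries between Glioma and Control was taken over the genes called in Glioma against Control. Of the 1152 higher genes, 484 (42.0%) were lower with Ca-alpha1T RNAi against Glioma and 411 (35.7%) were still higher than Control. With slo RNAi these were 383 (33.2%) and 493 (42.8%). Of the 663 lower genes, 266 (40.1%) were higher with Ca-alpha1T RNAi against Glioma and 200 (30.2%) still lower than Control, and 221 (33.3%) and 278 (41.9%) with slo RNAi. The median share of the Glioma log2 ratio that remained was 46.5% and 42.4% with Ca-alpha1T RNAi, for higher and lower genes, and 58.3% and 54.9% with slo RNAi. Simulated unchanged libraries shared Glioma and Control in the same way. There the share was taken for the Ca-alpha1T RNAi library only, over higher and lower genes together. It was 45.9% with counting error alone, on 29.8 called genes on average, and 49.8% at an assumed coefficient of variation of 0.3. A remaining share near 50% is thus what chance selection alone returned for the Ca-alpha1T RNAi library. No such share was simulated for slo RNAi. Genes chosen without the measured pair gave smaller shares called the opposite way, for higher and for lower genes. In Glioma against Control, higher genes chosen with slo RNAi and with Ca-alpha1T RNAi had medians of 1.30 and 1.31. The lower genes had −0.76 and −0.85, and so had less to return. Of 834 genes higher with slo RNAi than in Control, 200 were lower with Ca-alpha1T RNAi against Glioma and 94 higher, median −0.38. Independent lists would share 54.2 and 37.9. Of 691 chosen with Ca-alpha1T RNAi, 155 were lower with slo RNAi against Glioma and 82 higher, median −0.25, against 44.6 and 28.4. Of 678 genes lower with slo RNAi than in Control, 124 were higher with Ca-alpha1T RNAi against Glioma and 104 lower, median 0.21. Independent lists would share 31.2 and 44.7. Of 474 chosen with Ca-alpha1T RNAi, 89 were higher with slo RNAi against Glioma and 110 lower, median −0.06, against 19.4 and 30.5. Both directions thus exceeded independent lists, and in proportion the opposite calls did so more, for higher and for lower genes. For the 474 lower genes, however, more were called lower (110) than higher (89) with slo RNAi against Glioma, so no return towards Control is shown there.

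Across both knockdown comparisons against Glioma, 520 genes were called the same way and 56 opposite ways. The same direction held for 212 higher and 308 lower genes, where independent lists of these sizes would share 20.8 and 53.8. Across 11311 genes, which are not independent replicates, the correlation of the log2 ratios was 0.522 and the covariance 0.323. Unchanged libraries sharing Glioma gave a correlation of 0.501 and a covariance of 0.217 at an assumed coefficient of variation of 0.3, with 363 genes called the same way, and a covariance of 0.105 and 51.6 genes at 0.2. At 0.4 the covariance of 0.388 and the 958 genes were above the observed values, but that setting also gave a median absolute log2 ratio of 0.58, above those of both knockdown comparisons. With 1 Glioma library the reference cannot be split, and part of the excess over independent lists may come from the shared library. Both RNAi groups also carried a further UAS construct that Glioma lacked, and any effect of that cannot be told apart here. Pairs of comparisons with no library in common, chosen after seeing the data, gave correlations of −0.15 for Ca-alpha1T RNAi against Glioma with slo RNAi against Control and −0.07 for slo RNAi against Glioma with Ca-alpha1T RNAi against Control.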

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

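The counts of genes called in opposite directions and the list medians were planned, while the tests of explanations for the 3 patterns were chosen after the results were seen. A set of 15 named genes were called in opposite directions in the 2 knockdown comparisons against Glioma, and none of these differences was tested, since each group has 1 library. Among the antimicrobial genes, the log2 ratios with Ca-alpha1T RNAi and with slo RNAi were 5.81 and −1.12 for AttD, 3.86 and −3.98 for Def, 2.05 and −5.50 for DptA, 2.86 and −4.84 for DptB, and 2.07 and −2.62 for Drsl5. Among the cuticle genes they were 2.34 and −1.46 for Ccp84Aa, 1.44 and −1.54 for Ccp84Ab, 2.28 and −1.99 for Ccp84Ad, 4.46 and −1.73 for Lcp65Af, and 1.08 and −1.10 for Lcp65Ag1. Of the ecdysone-related and pigmentation genes, Edg78E stood at 1.50 and −2.49, Hr4 at 1.67 and −1.05, and ple at 2.01 and −1.62. The salivary genes ng1 and ng3 went the other way, at −2.35 and 1.20, and at −2.94 and 1.66. In all, 44 genes were higher with Ca-alpha1T RNAi and lower with slo RNAi, and 12 the reverse. Independent lists of these sizes would share 35.4 and 31.7. Simulated unchanged libraries sharing Glioma gave 2.55 opposite calls in all at an assumed coefficient of variation of 0.3.

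The salivary glue genes were lower in Glioma than in Control. Less salivary tissue in the sample would lower all salivary genes, and ng1, ng2 and ng3 had a median log2 ratio of 0.60, against −4.75 for the glue and Eig71E genes, but single libraries give no spread to decide this. An earlier point of the late larval ecdysone response in the Glioma larvae is a candidate explanation, as the ecdysone list, which shares no gene with the salivary list, had a median of −0.78, below the middle 95% of random lists, which ended at −0.24. With Ca-alpha1T RNAi against Glioma the ecdysone median was 0.59. That of the 9 glue and Eig71E genes was 1.30, with 4 higher and none lower. Both sets were taken up here because they were low in Glioma, the shared reference, so a rise against it cannot decide this. In the same comparison ng1, ng2 and ng3 had a median of −2.94. Against Control the ecdysone median with Ca-alpha1T RNAi was −0.20, while the salivary one was −2.67 with 12 of 14 genes lower. With slo RNAi the ecdysone list stayed low, at −0.56 against Control and 0.06 against Glioma, while the glue and Eig71E genes had a median of 3.03 against Glioma. There ng1, ng2 and ng3 had a median of 1.20, and all 14 salivary genes lay above 0. The timing, the amount of salivary tissue and a direct effect of the constructs thus stay open.

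Of 25 muscle genes, 18 were higher in Glioma than in Control and 7 were not called. More muscle in the dissected heads may be the source, but that 25 of 25 muscle genes lay above 0 restates the pattern and leaves it open. A smaller share of brain and disc RNA would raise every other tissue alike, and the neuroblast median of −0.58 and the neuronal one of −0.39 go with it. Fat body genes went both ways, 9 above 0 and 14 below. Their median of −0.0724 had an upper bound across genes of 0.39, against a lower bound of 1.19 for muscle. This argues against it as the whole cause only if the fat body genes were themselves unchanged, which was not tested. Medians of other tissues were 1.10 for cuticle, 0.36 for gut, 0.00 for hemocyte and −4.07 for salivary genes, so a part stays open. A change of these genes caused by the constructs was not tested.

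Pi3K92E was lower with slo RNAi than in Glioma, Egfr stood at −0.46 without passing the rule, and each technical explanation stays open, since the values come from single libraries. Fewer glia or a weaker driver would leave both with the same share of their excess over Control, and 34.2% remained for Pi3K92E and 65.6% for Egfr. Against fewer glia, repo stood at 0.06 and none of 31 glial genes was called, but the spread between libraries is not known. A division of Gal4 over 1 more UAS construct might lower Pi3K92E with Ca-alpha1T RNAi too, where it stood at −0.0366, and a smaller share of males might matter if the constructs were X-linked, as lncRNA:roX2 stood at −1.25 and lncRNA:roX1 at −0.92, but the constructs' chromosomes are not known here. An effect of slo RNAi itself was not tested.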

How the results depend on the processing

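The alternatives were fixed before the data were examined, except library sizes without the mitochondrial large ribosomal RNA, chosen after seeing the data, which kept all 6 counts of genes it was tried on within 1.5 times. No paired analysis was possible because each group has 1 library. DESeq2 size factors, a prior count of 5 and no filter left every count of genes within 1.5 times of its main value. Of 1224 list medians under the alternatives, 1002 stayed within their interval, 208 moved and 14 reversed, where reversed counts only lists outside the middle 95% of random lists. The sign changed for 95 medians in all. Of 2673 values of named genes 1774 stayed and 899 moved. No called gene changed sign, while 11 values of genes not called did, among them Ca-alpha1T in its own RNAi library. Total counts shift all ratios of a comparison alike, so a change of sign there is no change relative to other genes. Calls of named genes were lost more often. Of 109 called in Glioma against Control, 89 with Ca-alpha1T RNAi and 72 with slo RNAi against Glioma, 9, 9 and 3 were no longer called on total counts, 25, 25 and 23 on FPKM, 24, 20 and 21 on TPM, and 58, 52 and 37 at 4-fold.

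At 4-fold, genes higher and lower were 315 and 192 in Glioma against Control, 136 and 183 with Ca-alpha1T RNAi against Glioma, and 145 and 221 with slo RNAi against Glioma. Against Control they were 194 and 135 with Ca-alpha1T RNAi and 194 and 212 with slo RNAi, and 211 and 158 between the knockdown libraries. Total counts gave 1024 genes lower in Glioma against Control, and 975 higher and 472 lower with Ca-alpha1T RNAi against Glioma. At least 50 counts gave 315 genes higher with slo RNAi against Glioma.

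The authors' FPKM gave 497 genes higher in Glioma against Control, 270 lower with Ca-alpha1T RNAi against Glioma, and 211 higher and 386 lower with slo RNAi against Glioma. It gave 338 higher and 229 lower with Ca-alpha1T RNAi against Control, 252 higher with slo RNAi against Control, and 166 lower with Ca-alpha1T RNAi against slo RNAi. The authors' TPM gave 512 higher in Glioma against Control, 942 higher and 232 lower with Ca-alpha1T RNAi against Glioma, and 284 higher and 410 lower with slo RNAi against Glioma. It gave 228 lower with Ca-alpha1T RNAi against Control, 321 higher with slo RNAi against Control, and 173 lower with Ca-alpha1T RNAi against slo RNAi.

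In Glioma against Control, the ion channel median reversed to −0.0198 on FPKM and −0.0734 on TPM, the extracellular matrix median to −0.014 on TPM, and the ribosome biogenesis median to −0.0649 on total counts, −0.084 on FPKM and −0.15 on TPM. On total counts the median of all genes was −0.22, so the ribosome biogenesis median still lay above it. With Ca-alpha1T RNAi against Glioma on TPM, the medians reversed to 0.0323 for cuticle, 0.12 for gut, 0.14 for ribosomal proteins and 0.14 for ribosome biogenesis, and the muscle median moved to −0.66. With slo RNAi against Control the ion channel median reversed to −0.0197 on FPKM and −0.018 on TPM, and with Ca-alpha1T RNAi against slo RNAi the ribosomal protein median to 0.0041 on FPKM and 0.12 on TPM.

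Of the genes higher in Glioma than in Control with at least 50 counts, 32.1% were still called against Control with Ca-alpha1T RNAi, and 42.7% of the log2 ratio remained. Of the lower genes with at least 50 counts, 35.4% were called the opposite way against Glioma with Ca-alpha1T RNAi and 25.2% with slo RNAi. At 4-fold, 21.3% of higher genes were called the opposite way with Ca-alpha1T RNAi, 28.6% were still called and 57.8% of the ratio remained, against 22.9% opposite and 27.0% still called with slo RNAi. Of lower genes at 4-fold, 29.7% were opposite with Ca-alpha1T RNAi with 46.7% remaining, and 35.9% were still called with slo RNAi. For genes chosen from the other knockdown library against Control, 23.98% of higher and 18.3% of lower genes were opposite with Ca-alpha1T RNAi, and 40.5% and 33.9% still called. With slo RNAi these were 22.4% and 18.8% opposite, and 48.9% and 48.5% still called.

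For the overlap of both knockdown comparisons, at least 50 counts gave a correlation of 0.552 and a covariance of 0.281. At 4-fold 103 genes went the same way and 7 opposite ways.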

Other observations

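Antimicrobial peptide genes did not move as 1 group across the libraries. Drs had 92, 153512, 4046 and 17973 counts in Control, Glioma, Ca-alpha1T RNAi and slo RNAi, while CecA1 had 9, 2, 3085 and 11, and DptA 1190, 2512, 10240 and 47. Genes chosen by the naming rule from different comparisons thus peaked in different libraries: Drs in Glioma, and the cecropin, attacin and diptericin genes CecA1, AttD and DptA with Ca-alpha1T RNAi.

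Several genes stood low or high in both knockdown libraries against Glioma. Both RNAi groups also carried a further UAS construct that Glioma lacked, and share the Glioma library as reference. These values therefore cannot be tied to the loss of either channel. Culd had 7441 counts in Control and 7842 in Glioma, against 346 with Ca-alpha1T RNAi and 426 with slo RNAi. The noncoding RNA gene lncRNA:SMRG stood at 5.15 and 5.59 against Glioma on 22 Glioma counts, and TwdlO at 5.80 and 6.08 on 4. The pigmentation gene y had 15 counts in Control, 205 in Glioma, 774 with Ca-alpha1T RNAi and 876 with slo RNAi.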
